A study of Homo sapiens with 18 samples.

How the data were processed

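RNA was measured by bulk sequencing in human monocytes purified from blood mononuclear cells, per the labels' protocols. The cells were plated for 24 h and treated for 6 h with PBS, LPS (lipopolysaccharide, 100 ng/mL), psilocybin (10 µM), MDMA (10 µM), or LPS with either compound. Libraries were made from 5 ng of total RNA, per the labels' protocols. The labels give 6 groups with 3 libraries each, 18 in all, and do not say whether a replicate number marks a donor, a culture or a day. p-values therefore measure only the spread between these samples, which may be technical.

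The authors deposited raw gene counts, as 1 table of 55765 gene symbols with a column for each library and as 18 single-sample files, which hold the same values as the table. Per the submitters' processing notes, the tools were fastp 0.23.2, FastQC 0.11.9, MultiQC 1.11, featureCounts 2.0.1 and edgeR 3.42.4, with the genome build hg19. The aligner, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies, such as the metallothioneins, CCL3, CXCL2, CXCL3, NT5C3AP1, RN7SK and RNU2-59P, are therefore uncertain. Symbols are those of the deposited counts (IL8 is CXCL8 and IRG1 is ACOD1).

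Each library's total count, detected genes and most abundant genes were checked first. The library labelled MDMA 3 held 9 counts, under a minimum of 100000 set for a usable library, and was left out. Replicates were compared with a chi-square test over genes with at least 20 counts in the pair. LPS 1 and LPS 2 gave a chi-square per degree of freedom of 1.04 over 8574 genes (chi-square p = 0.0101), against 10 to 91.2 in the other 15 pairs within groups, so their counts were summed and used as 1 library, LPS 1-2. The fit had been planned for 18 libraries, and it used 16: PBS 3, LPS 2, psilocybin 3, MDMA 2, LPS+psilocybin 3 and LPS+MDMA 3. The smallest of these held 299466 counts (LPS+psilocybin 3), and the others from 2183723 to 6738447 before the summing.

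Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, filterByExpr and 1 fit of all 6 groups with 10 residual degrees of freedom. It kept 12403 genes, with a common biological coefficient of variation of 36% and prior degrees of freedom of 4.07. Adjusted p is the Benjamini-Hochberg value over the genes tested, and a gene rose or fell where it was under 0.05. Standard errors are of the log2 fold change, calculated back from the F statistic as its absolute value over the square root of F. Intervals of folds are at 95% and symmetric on the log2 scale, so they are approximate for genes with few counts in a group. CPM are the cpm values of edgeR after TMM scaling, given as mean ± SD over libraries. The comparisons were each treatment with PBS, each combination with LPS, the difference of each compound's effect with and without LPS (interaction), and the compounds with each other at the matched dose and time. For a gene with 0 counts throughout a group, the fitted fold is replaced in the text by a lower bound from a floor of 3 counts over the group. Intervals and floors cover counting error only where counts alone set them, since the reads carry no molecular identifiers.

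A total of 34 gene lists with 575 symbols was fixed before the data were examined, as were the tests, the comparisons, the rule for named genes and most of the alternatives. The lists cover inflammatory, interferon, early response, stress, metabolic, receptor and regulatory genes, marker genes of monocytes and of other blood cells, and technical groups. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and with an estimated correlation beside it, for the 29 lists with at least 5 tested members. List p-values are adjusted over the lists within a comparison. camera compares a list with all other genes, while fry, used as an alternative, tests whether a list's genes move on balance one way. Genes are named by rule: the 8 largest rises and 8 largest falls among genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, or, where fewer than 3 passed, the 3 with the smallest p in each direction. Up to 4 members of each list and a panel of cytokines, receptors and targets were also named. Clone-style names, immune receptor segments and sex-linked genes were not named. 1 gene that the rule selects is not reported here.

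The genes higher or lower with LPS, by at least 2-fold, were taken from LPS+MDMA against MDMA to test LPS+psilocybin against LPS, because these comparisons share no library. For LPS+MDMA against LPS the set came from LPS+psilocybin against psilocybin. A library's LPS position is its median place on the log2 CPM scale between the MDMA mean (0) and the LPS+MDMA mean (1). The correlation of both compounds' effects was set beside 20 simulations of unchanged groups that shared the same controls. GC content and length came from GENCODE v29 transcripts on GRCh38, matched by symbol for 11100 of the 12403 genes (89.5%, against a required 80%), and no coordinates were used.

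Alternatives were other scaling factors, filters, thresholds and libraries in the fit, a replicate block, robust dispersion, limma-voom with and without library weights, DESeq2 1.42.0, and leaving out each library. Added after the data were seen were fits without psilocybin 1 and LPS+psilocybin 3, whose profiles stood apart, fits with 18 and 17 libraries, GC correction, and a block that gave LPS 1-2 the other number. So was leaving out each library for the correlation of the compounds' effects. The pipeline was tested on simulated data with 200 changed genes, and recovery below refers to edgeR at adjusted p under 0.05. Of 100 genes changed 2-fold and 100 changed 4-fold it found 4% and 50% for LPS against PBS with 12159 genes run, 8% and 55% for psilocybin against PBS (12105), and 5% and 42% for MDMA against PBS (12157). It found 1% and 31% for LPS+psilocybin against LPS (12105), and 2% and 29% for LPS+MDMA against LPS (12118). From 0 to 3 unchanged genes were called by edgeR. DESeq2 called 12 to 19 unchanged genes among 81 to 113 calls per comparison. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.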

Results

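The series holds RNA-seq counts of human blood monocytes treated for 6 h, collected to examine anti-inflammatory properties of MDMA and psilocybin. Total counts were 6205866, 5924119 and 4815237 in PBS 1 to 3, and 4249663, 4443792 and 3969005 in psilocybin 1 to 3. MDMA 1 and MDMA 2 held 6738447 and 6493581 counts, and MDMA 3 held 9 and was left out. LPS 1, LPS 2 and LPS 3 held 2183723, 2246173 and 4351334 counts. LPS 1 and LPS 2 differed by little more than the sampling noise (chi-square per degree of freedom 1.04, chi-square p = 0.0101, against 10 or more in the other pairs within groups) and were counted as 1 sample, LPS 1-2. LPS+psilocybin 1 to 3 held 3722274, 4018564 and 299466 counts, and LPS+MDMA 1 to 3 held 4852910, 3639793 and 4669214. The groups compared were PBS (n = 3), LPS (n = 2), psilocybin (n = 3), MDMA (n = 2), LPS+psilocybin (n = 3) and LPS+MDMA (n = 3). Some libraries stood apart from their groups. LPS+MDMA 3 had a chi-square per degree of freedom of 78.8 and 58.9 to LPS+MDMA 1 and 2, which differed by 10. Of its counts 2.597% were mitochondrial, against 1.423% and 1.929% in LPS+MDMA 1 and 2. The only MDMA libraries in the fit, MDMA 1 and MDMA 2, differed by 70.3. MDMA 1 lay nearer to psilocybin 2 (25.7) and MDMA 2 nearer to PBS 2 (26). PBS 1 differed from PBS 3 by 60.8 and from PBS 2 by 28.6. On the scale where the MDMA mean is 0 and the LPS+MDMA mean is 1, psilocybin 1 lay at 0.776 over 640 genes higher with LPS, against 0.076 and 0.04 in psilocybin 2 and 3, and LPS+psilocybin 3 lay at 0.486, against 0.879 and 0.895 in LPS+psilocybin 1 and 2.

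**Figure D1:**
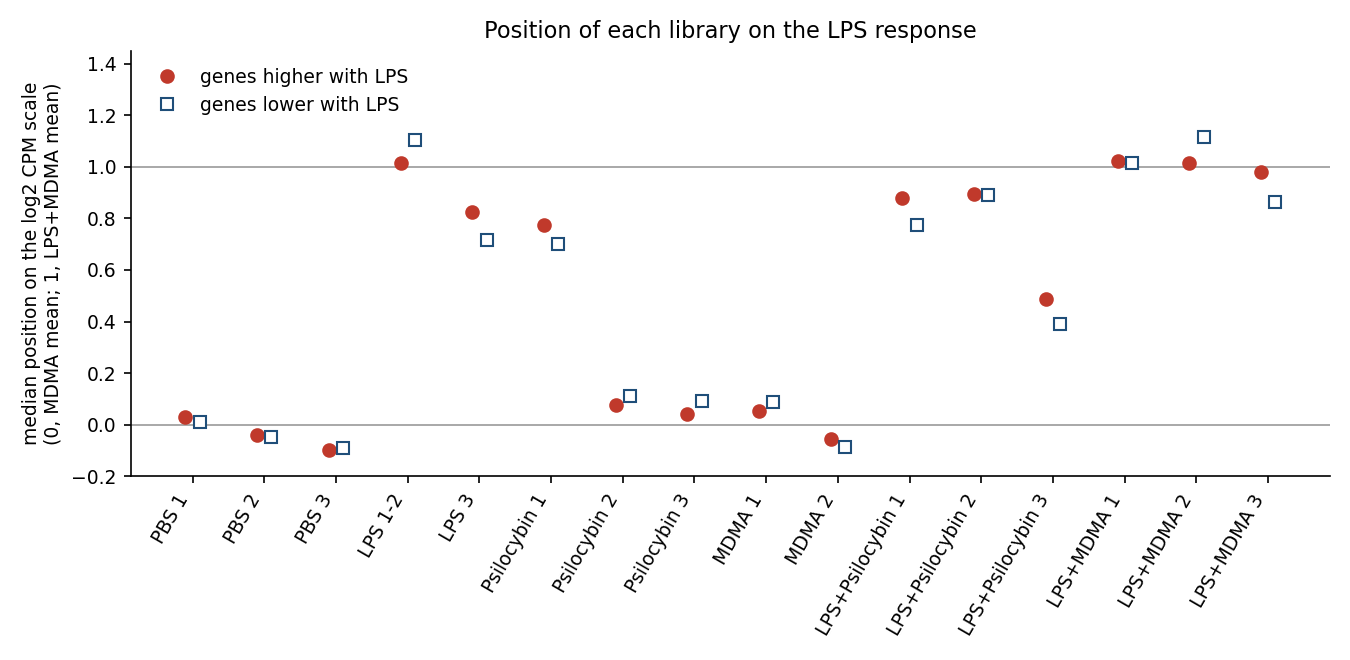
LPS position of each library (vertical axis, median place on the log2 CPM scale, 0 for the MDMA mean and 1 for the LPS+MDMA mean) by group (horizontal axis). Circles are the median over 640 genes higher with LPS and squares the median over 619 genes lower with LPS. Psilocybin 1 lies at 0.776 and LPS+psilocybin 3 at 0.486, each away from the other libraries of its group.

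LPS, a bacterial ligand of TLR4, was compared with PBS to give the inflammatory response against which the compounds are read. IL12B, the subunit shared by IL-12 and IL-23, rose from a mean of 0.734 CPM (0 to 2.01 in 3 libraries) to 475 ± 77.7 CPM (SD, n = 2), a 586-fold rise (95% interval 30.8 to 11200). PTX3, a secreted pattern recognition protein, rose 395-fold (55.7 to 2800), and IL8, the neutrophil chemokine, rose from 1727 ± 1890 to 75100 ± 19500 CPM, 43.5-fold (7.32 to 258). TNF rose 21.1-fold (5.44 to 81.4), from 2.56 ± 1.92 to 56 ± 13.7 CPM. Genes with no count in the PBS libraries were at least 562-fold higher (IRG1, the enzyme that makes itaconate), at least 140-fold (RHCG, an ammonia transporter) and at least 129-fold (IL20). The same bound was at least 75.2-fold for LINC00515, 73.4-fold for the adenosine receptor ADORA2A and 70.2-fold for the metalloelastase MMP12. Without LPS 1-2 the bounds were 174-fold for IRG1, 73.2-fold for RHCG, 63.4-fold for IL20 and 29.3-fold for LINC00515, and without LPS 3 the bound of MMP12 was 18.3-fold. Leaving out PBS 1, which raises the floor, gave 348-fold for IRG1, 86.9-fold for RHCG, 79.9-fold for IL20, 46.6-fold for LINC00515, 45.5-fold for ADORA2A and 43.5-fold for MMP12. The falls named by rule were ACSF2 (at least 16.3-fold lower) and AMDHD1 (at least 9.31-fold lower), with no count in the LPS libraries (7.65-fold and 4.37-fold without LPS 3), and IQCD, GPR34, CD1D, NFIA, CNPY4 and PDK4. PDK4, an inhibitor of pyruvate dehydrogenase, fell from 253 ± 136 to 5.01 ± 2.85 CPM, a log2 fold change of −5.66 (SE 1.82, adjusted p = 0.0362).

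Inflammatory lists rose together with LPS. Of 20 tested proinflammatory cytokines, 18 rose (20 adjusted over the list alone), with a median log2 fold change of 5.14 that is the same with IL20 at its bound, and OSM rose 17.7-fold and IL27 352-fold. Of 18 chemokines 13 rose (14 over the list alone), among them CCL2, 37.9-fold (8.2 to 175), and CXCL3, 49.6-fold. Of 22 NF-kB pathway and feedback genes 20 rose (22 over the list alone), with NFKB2 up 13.1-fold and TRAF1 61.2-fold. All 36 interferon-stimulated genes rose, with OAS3, an antiviral RNA sensor, up 86.9-fold (16.4 to 459) and CXCL11 up 168-fold. Of 25 immediate early genes 13 rose (14 over the list alone), JUN 4.72-fold (2.92 to 7.61) and IER3 21.4-fold, and of 21 anti-inflammatory regulators 9 rose (11), with SOCS3, an inhibitor of cytokine signalling, up 76.5-fold. The adjusted camera p was 3.55e-10 for cytokines, 1.18e-07 for chemokines, 4.66e-12 for NF-kB, 2.38e-18 for interferon, 1.75e-08 for immediate early and 1.56e-04 for anti-inflammatory genes. With an estimated correlation adjusted p = 0.262 for the first 4 of these lists and 0.0999 for the others. Once psilocybin 1 and LPS+psilocybin 3 were left out it was 0.00886 for interferon-stimulated genes, 0.151 to 0.207 for the other 5 lists and 0.031 for the apoptosis regulators below.

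Apoptosis and metabolic genes also differed. Of 20 apoptosis regulators 7 rose and 1 fell (11 and 1 over the list alone), with BCL2 up 9.98-fold and MCL1 6.38-fold (camera adjusted p = 1.4e-04, adjusted p = 0.0999 with an estimated correlation). PMAIP1 and BCL2L1 rose as well, with log2 fold changes of 2.82 to 3.72 and 1.36 to 1.82 with each library left out. Of 23 glycolysis and hypoxia genes 9 rose (9 over the list alone, 0.00189, adjusted p = 0.262 with an estimated correlation). Of 25 nuclear genes of oxidative phosphorylation 5 fell (4 over the list alone) and all 25 estimates were negative, with COX5B at 0.336-fold (0.00327, adjusted p = 0.448 with an estimated correlation). CD14, the LPS co-receptor, fell to 0.22-fold (0.106 to 0.457), from 1105 ± 471 to 243 ± 34.2 CPM, and HLA-DMB, which loads peptide onto MHC class II, fell to 0.11-fold (adjusted p = 0.00508). TLR4 had a log2 fold change of −1.11 (SE 0.66, adjusted p = 0.226). MAOA, which degrades serotonin, rose 8.96-fold (5.12 to 15.7, adjusted p = 7.25e-04).

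In all, 1737 genes rose and 1355 fell with LPS (edgeR). With upper quartile factors, which move the median of all genes by −0.17, 1429 rose and 1860 fell. Leaving out psilocybin 1 and LPS+psilocybin 3 gave 2085 and 1789 genes, with 3071 of the same genes called. The 3092 calls became 1670 without PBS 2, 1791 without PBS 3, 470 without LPS 1-2 and 1593 without LPS 3, and DESeq2 and limma-voom gave 3679 and 3265. Of the genes named above, IL20 (adjusted p = 0.0671), LINC00515 (0.0624), ACSF2 (0.0703), IQCD (0.0993), CNPY4 (0.0682), CD14 (0.102) and COX5B (0.0502) were not called without LPS 1-2, and MMP12 (0.0527) without LPS 3. ADORA2A (0.0519 to 0.0788) lost its call without PBS 2 or LPS 1-2, and CD1D (0.0683 to 0.0985) without LPS 1-2 or LPS 3. AMDHD1 (0.0562 to 0.14) lost it without PBS 3, LPS 1-2 or LPS 3. Leaving out PBS 1 raised the log2 fold changes of IL12B to 12.05, IL8 to 6.85, TNF to 5.15, CXCL11 to 8.97 and CD80 to 9.10. Without LPS 1-2 they were 7.65 for PTX3, 4.95 for CXCL3 and −6.38 for PDK4. PDK4 (0.0677 to 0.182), NFIA (0.0629 to 0.177) and GPR34 (0.0521 to 0.215) lost it without PBS 2, PBS 3, LPS 1-2 or LPS 3, and GPR34 also without LPS 1.

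**Figure D2:**
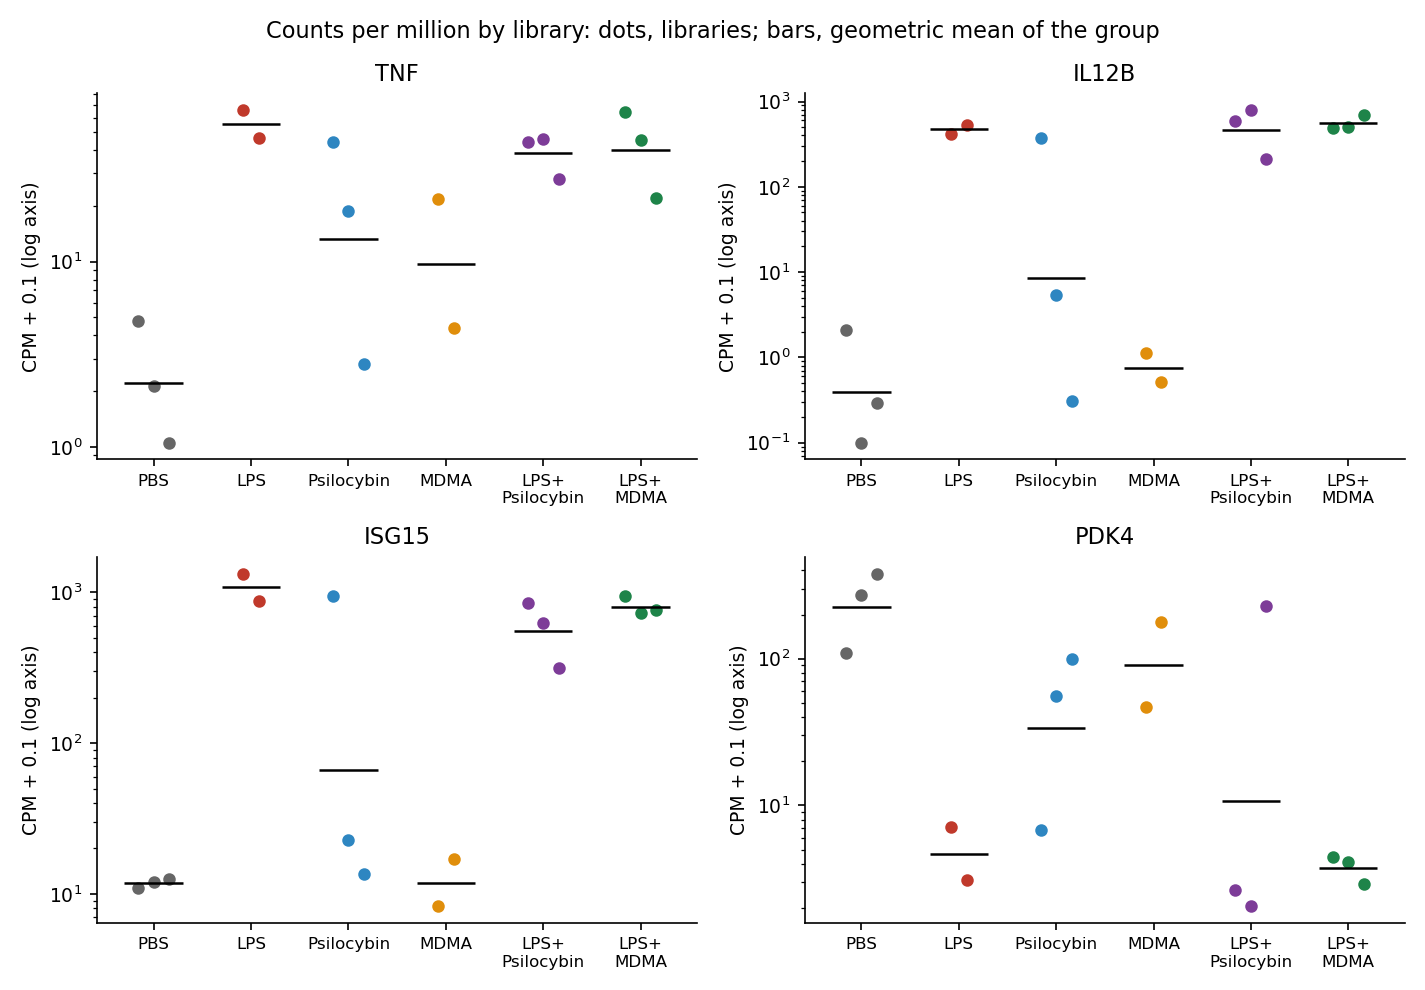
TNF, IL12B, ISG15 and PDK4 in each library (vertical axis, CPM plus 0.1, log scale) by group (horizontal axis). Dots are libraries and bars the geometric mean of the group. IL12B averaged 0.734 CPM with PBS and 475 CPM with LPS, and 1 psilocybin library lies near the LPS libraries for IL12B and ISG15.

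Psilocybin, the precursor of the serotonin receptor agonist psilocin, was compared with PBS to ask what it does to monocytes at rest. SLC7A5, an amino acid transporter, rose 28.6-fold (14.6 to 56, adjusted p = 4.75e-04), from 3.62 ± 0.516 to 104 ± 37.1 CPM (n = 3 each). JUN, an AP-1 transcription factor, rose 4.65-fold (2.97 to 7.28), from 84.2 ± 5.39 to 391 ± 41.9 CPM, and DUSP1, a phosphatase that inactivates MAP kinases, rose 4.46-fold (2.66 to 7.49). NFKBIE, an inhibitor of NF-kB, rose 9.3-fold (4.66 to 18.5) and NFKB2 7.78-fold (3.81 to 15.9). BCL2 (5.33-fold), MCL1 (3.74-fold), the chaperone genes BAG3 (4.7-fold) and HYOU1 (3.09-fold), and JUNB (6.53-fold) rose as well. C8orf44 fell to 0.193-fold (adjusted p = 0.00739). SLC7A5, JUN, DUSP1, NFKBIE, NFKB2, BCL2, MCL1, BAG3, HYOU1, JUNB and C8orf44 kept their calls with each library left out.

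Immediate early genes were higher with psilocybin as a list. All 25 tested had positive estimates, and 12 of them rose (17 adjusted over the list alone), with a median log2 fold change of 1.63 (camera adjusted p = 9.38e-11, adjusted p = 0.118 with an estimated correlation). With psilocybin 1 and LPS+psilocybin 3 left out, 13 of the 25 rose (4.14e-13, adjusted p = 0.121 with an estimated correlation). Of 8 aryl hydrocarbon receptor targets 2 rose (4 over the list alone, camera adjusted p = 0.00937, adjusted p = 0.179 with an estimated correlation). They were TIPARP, 2.44-fold, and AHRR, the repressor of this receptor, with a log2 fold change of 1.36. Of 19 genes of the unfolded protein and amino acid stress response 3 rose (5 over the list alone, 0.00699, adjusted p = 0.499 with an estimated correlation). All 25 ribosomal protein genes had negative estimates, with 0 past the threshold and a median of −0.37 (3.77e-04, adjusted p = 0.617 with an estimated correlation), and 2 of 25 oxidative phosphorylation genes fell, COX5B to 0.494-fold (4.83e-04, adjusted p = 0.508 with an estimated correlation). All 8 histone genes and nuclear RNAs, a technical list, had negative estimates, and 1 fell (median −0.55, 0.0132, adjusted p = 0.499 with an estimated correlation). Without psilocybin 1 and LPS+psilocybin 3, 2 of these 8 fell (camera adjusted p = 0.00121, adjusted p = 0.121 with an estimated correlation). TIPARP and COX5B lost their calls without PBS 2 or PBS 3 (adjusted p = 0.0586 to 0.0796 and 0.0568 to 0.0676), and AHRR also without psilocybin 2 (0.0891 to 0.128).

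**Figure D3:**
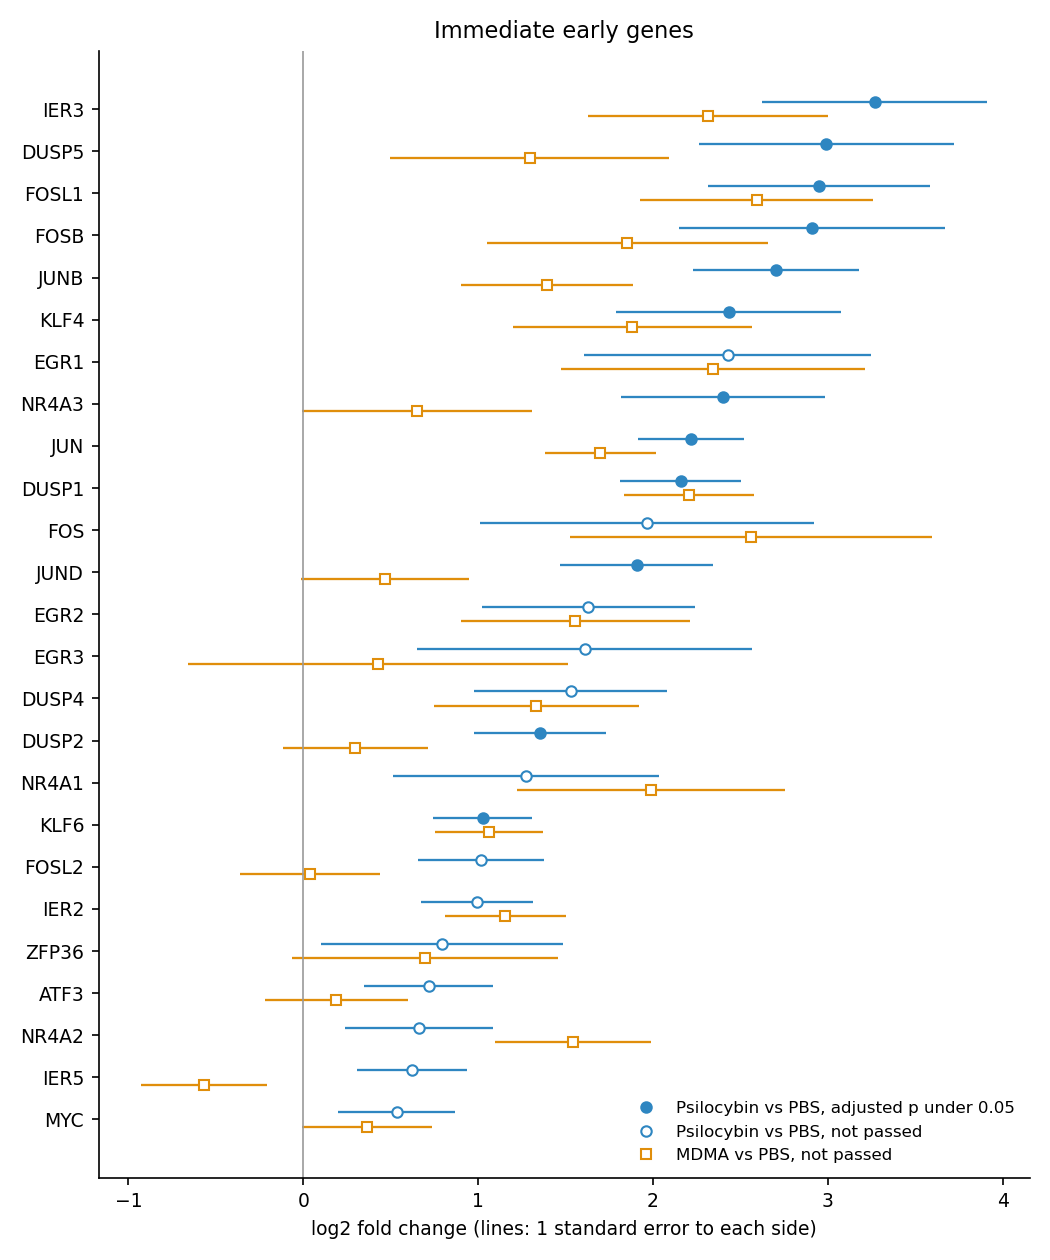
Log2 fold change ± 1 SE (horizontal axis) of the 25 tested immediate early genes (vertical axis) for psilocybin against PBS (circles, filled where adjusted p was under 0.05) and MDMA against PBS (squares). All 25 psilocybin estimates and 24 of the 25 MDMA estimates lie above 0, and 12 of the psilocybin estimates are filled.

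Inflammatory genes differed widely between the psilocybin libraries, with psilocybin 1 at 0.776 on the LPS scale. IL12B was called at 154-fold (10.1 to 2350, adjusted p = 0.0266), with 370 CPM in psilocybin 1 and 5.32 and 0.209 CPM in psilocybin 2 and 3. ISG15, an interferon-induced ubiquitin-like protein, was called at 27.9-fold (4.63 to 169), with 948, 22.8 and 13.4 CPM. TNF was called at 8.14-fold, with 43.9, 18.6 and 2.72 CPM. Of 20 cytokines 8 rose (16 over the list alone, camera adjusted p = 1.23e-05), of 18 chemokines 8 (13, 1.02e-04), of 22 NF-kB genes 7 (14, 2.63e-07) and of 36 interferon-stimulated genes 12 (28, 3.08e-05). With an estimated correlation adjusted p = 0.508 for the first 3 lists and 0.617 for the interferon list. Without psilocybin 1 and LPS+psilocybin 3, 0 of the 20 cytokines, 2 of the 18 chemokines, 3 of the 22 NF-kB genes and 2 of the 36 interferon-stimulated genes rose by edgeR, and 1 interferon-stimulated gene fell. Over the lists alone 4, 2, 5 and 2 rose, and 1 cytokine and 1 interferon-stimulated gene fell. The cytokine, chemokine and NF-kB lists still passed (camera adjusted p = 0.0205, 0.0116 and 0.00121, adjusted p = 0.726 with an estimated correlation), and the interferon list did not (0.62, median −0.08). IL12B then had a log2 fold change of 1.80 (adjusted p = 0.307), ISG15 of 0.63 (0.281) and TNF of 2.01 (0.168). IL12B (0.0502 to 0.357), ISG15 (0.0798 to 0.408) and TNF (0.0561 to 0.165) lost their calls without PBS 1, PBS 2, PBS 3 or psilocybin 1, and TNF also without psilocybin 2. With each library left out their log2 fold changes ran from 1.8 to 10.13, from 0.63 to 5.36 and from 2.01 to 3.78.

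The other genes named by rule were KCNK5 (at least 14.2-fold higher, with no count in PBS, 2.67-fold without psilocybin 1 and 8.8-fold without PBS 1), DNAAF1 and NEURL3, which were not called without PBS 1, PBS 2, PBS 3 or psilocybin 1 (adjusted p = 0.0873 to 0.16, 0.073 to 0.339 and 0.0787 to 0.191). PTX3 rose 49-fold with psilocybin, and it lost its call without the same libraries (0.0527 to 0.0797), with a log2 fold change of 2.62 in place of 5.61 without psilocybin 1. EMILIN1 lost its call without any PBS library or psilocybin 3 (0.0681 to 0.104), and CMPK2, which rose 37.7-fold, without PBS 2 or PBS 3 (0.0797 to 0.0803). Without psilocybin 1, at 0.776 on the LPS scale, CMPK2 had a log2 fold change of 1.99. That of NFKB2 was 2.27 without the same library, and that of CXCR4 −3.63 without psilocybin 3. Among falls, CXCR4, the receptor of CXCL12, went to 0.138-fold (0.0503 to 0.379), from 157 ± 77.7 to 21.5 ± 15.4 CPM, and RGS2, a regulator of G protein signalling, to 0.18-fold. CXCR4 (0.0605 to 0.0864), TMEM71 (0.0611 to 0.109) and DPEP2 (0.118 to 0.159) lost their calls without PBS 2, PBS 3, psilocybin 1 or psilocybin 2, and RGS2 (0.0635 to 0.0712) without PBS 2 or PBS 3. KLRB1 (0.0733 to 0.0976) lost it without PBS 2, PBS 3 or psilocybin 2, NT5C3AP1 (0.0581 to 0.0834) without all but psilocybin 1, and RN7SK (0.0844 to 0.152) without all but PBS 1. In all, 889 genes rose and 203 fell with psilocybin (edgeR), and 774 and 139 without psilocybin 1 and LPS+psilocybin 3, with 729 of the same genes called. With upper quartile factors, which move the median by −0.11, 760 rose and 387 fell. The 1092 calls became 628 without PBS 1, 164 without PBS 2, 152 without PBS 3 and 628 without psilocybin 2, and DESeq2 gave 2008.

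Fold changes of psilocybin against PBS rose with GC content. The correlation across 11100 genes was 0.379, and genes are not independent replicates. The median log2 fold change was −0.35 in 359 genes below 36% GC and 0.93 in 1325 genes above 60%. Once the GC trend of each library was taken out, 524 genes rose and 243 fell, against 819 and 278 of the same genes without the correction, with 562 called in both. The same correlation was 0.298 for MDMA, 0.124 for LPS, −0.071 for LPS+psilocybin against LPS and −0.088 for LPS+MDMA against LPS. For the interactions it was −0.305 (psilocybin) and −0.269 (MDMA), and for the compounds −0.223 without and 0.003 with LPS. In the psilocybin interaction 303 genes fell and 111 rose after the correction, against 417 and 92 of the same genes without it, with 312 called in both.

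**Figure D4:**
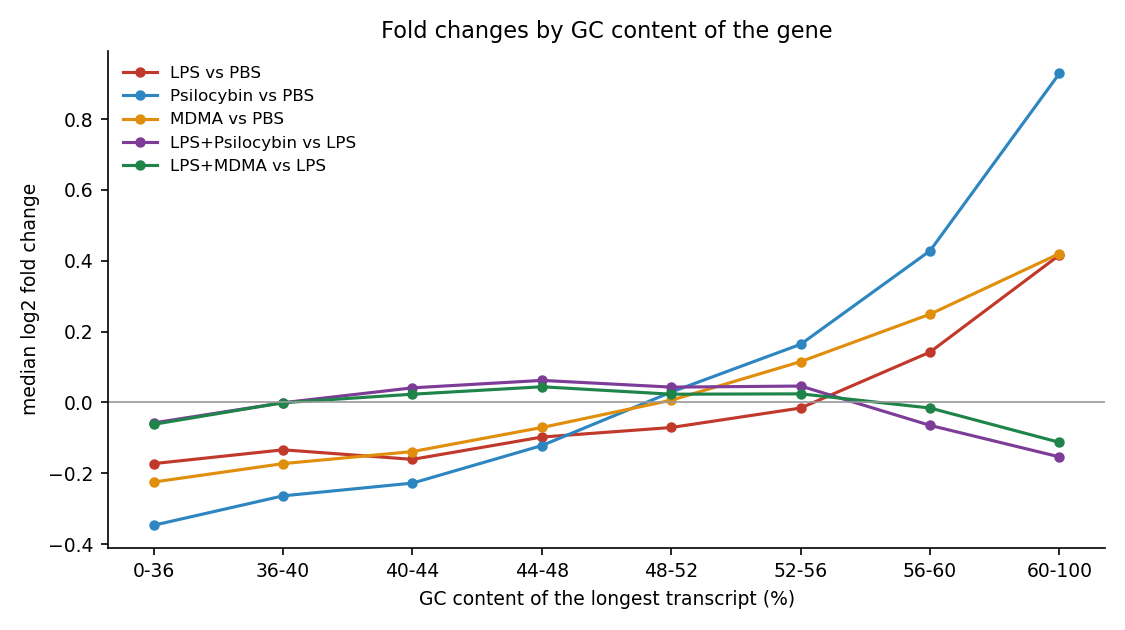
Median log2 fold change (vertical axis) of genes in 8 bins of the GC content of the longest transcript (horizontal axis, percent) for 5 comparisons (lines). For psilocybin against PBS the median goes from −0.35 below 36% GC to 0.93 above 60%.

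MDMA, an amphetamine that releases serotonin, was compared with PBS in the same way. No gene passed (edgeR, 0 of 12403, with 1077 at unadjusted p under 0.05 where chance gives 620). limma-voom gave 0 and DESeq2 58, but in simulated data for this comparison DESeq2 called 12 unchanged genes and edgeR 1. The smallest p-values among higher genes were those of TIPARP, 3.59-fold (2.31 to 5.57, adjusted p = 0.222), DUSP1, 4.61-fold (2.65 to 8.01, 0.222), and SLC7A5, 5.66-fold (2.9 to 11, 0.233). Among lower genes they were C1orf63 at 0.351-fold (0.233), CREBRF at 0.26-fold (0.233) and MS4A14 (log2 fold change −1.45, 0.304). JUN was at 3.25-fold (2.02 to 5.22, 0.233) and FOSL1, another AP-1 gene, at a log2 fold change of 2.59 (SE 0.66, 0.418). TNF was at 2.30 (SE 0.89, adjusted p = 0.513) and IL6 at 3.41 (SE 1.92, 0.647), which turned to −5.48 without MDMA 1.

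As lists, 2 groups stood out with MDMA under both correlations. Of 25 immediate early genes 24 had positive estimates, with a median log2 fold change of 1.33, 0 past the threshold over all genes and 11 adjusted over the list alone (camera adjusted p = 5.26e-12, adjusted p = 0.0366 with an estimated correlation). All 8 aryl hydrocarbon receptor targets had positive estimates, with a median of 0.79 and 1 past the threshold over the list alone (1.63e-04, adjusted p = 0.0356 with an estimated correlation). The estimated correlation gave adjusted p = 0.0683 and 0.0644 for these lists without psilocybin 1 and LPS+psilocybin 3. The unfolded protein and amino acid stress list had 3 of 19 genes past the threshold over the list alone (1.93e-05, adjusted p = 0.134 with an estimated correlation). The list of aryl hydrocarbon receptor targets holds IL1B and SERPINB2, of which SERPINB2 rose 124-fold with LPS (log2 fold change 6.96, and 5.10 without LPS 1-2 or 7.75 without LPS 3). Technical lists moved too: all 8 histone genes and nuclear RNAs had negative estimates (median −0.52, 0.00125, adjusted p = 0.197 with an estimated correlation), as had 22 of 25 ribosomal protein genes (0.0195, adjusted p = 0.745 with an estimated correlation). Cytokines, with 17 of 20 estimates positive, and chemokines, with 13 of 18, were higher as lists (camera adjusted p = 7.92e-04 and 0.00125, adjusted p = 0.604 with an estimated correlation). In both, 0 genes were past the threshold over all genes or over the lists alone. MDMA 1 and MDMA 2 differed by a chi-square per degree of freedom of 70.3. Without MDMA 1 the log2 fold changes of IL6 and IL1B reversed to −5.48 and −1.13, while 14 of 16 named values did not reverse.

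LPS+psilocybin was compared with LPS to ask whether psilocybin alters the response to LPS. No gene passed (edgeR, 557 at unadjusted p under 0.05 where chance gives 620; limma-voom and DESeq2 gave 0). TNF was at 0.734-fold (0.212 to 2.53), IL6 at 0.541-fold (0.0492 to 5.94), IL1B at 0.952-fold (0.105 to 8.65) and CXCL10 at 0.597-fold (0.0671 to 5.31), each with adjusted p = 1. The estimate of IL1B turned positive without LPS 1-2 (0.24) or LPS+psilocybin 3 (0.29). Among the smallest p-values were those of FLNA, an actin crosslinker, at 0.271-fold (0.147 to 0.501), BAZ2A, RMDN2, ZNF37BP and QARS, at 1.9-fold (1.35 to 2.67), all with adjusted p = 1. The median 95% interval reached 1.95-fold to either side, and in simulated data 1% of 2-fold and 31% of 4-fold changes were found in this comparison. No gene list passed with camera, and 35 of 36 interferon-stimulated genes had negative estimates (median −0.46, adjusted p = 0.0769), with LPS+psilocybin 3 at 0.486 on the LPS scale. Without it and psilocybin 1 the interferon median was −0.15 (camera adjusted p = 0.531).

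The 810 genes higher with LPS in LPS+MDMA against MDMA had a median log2 fold change of −0.30 in LPS+psilocybin against LPS (camera p = 3.33e-09, p = 0.382 with an estimated correlation), with 169 positive. The 779 genes lower with LPS had a median of 0.29 (8.12e-15, p = 0.219 with an estimated correlation), with 599 positive. LPS+psilocybin 3 stood at 0.486 on the LPS scale. Without it and psilocybin 1 the medians were −0.07 over 1111 genes (camera p = 0.132 in the limma package) and 0.07 over 1192 genes (limma camera p = 0.0171, p = 0.579 with an estimated correlation). The higher genes lost their call without LPS 1-2 (−0.04) or LPS+psilocybin 3 (−0.09), and the median of the lower genes was −0.03 without LPS 1-2 and 0.09 without LPS+psilocybin 3. Leaving out LPS 3 moved the medians the other way, to −0.60 and 0.68, as did LPS+psilocybin 1 (−0.46 for the higher genes) and LPS+psilocybin 2 (−0.47 and 0.45).

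LPS+MDMA was compared with LPS for the same question. No gene passed (edgeR, 532 at unadjusted p under 0.05 where chance gives 620). limma-voom gave 0 and DESeq2 38, but in simulated data for this comparison DESeq2 called 16 unchanged genes and edgeR 1. TNF was at 0.785-fold (0.234 to 2.64), IL6 at 0.869-fold (0.0787 to 9.59), IL1B at 1.27-fold (0.137 to 11.8) and CXCL10 at 0.962-fold (0.107 to 8.7), each with adjusted p = 1. The estimate of IL6 turned positive without LPS 1-2 (0.28) or LPS+MDMA 3 (0.37), and that of CXCL10 without LPS 1-2 (0.47), LPS+MDMA 2 (0.07), LPS+MDMA 3 (0.24) or LPS 2 (0.02). NR4A2, an early nuclear receptor gene, was at 4.96-fold (2.39 to 10.3, adjusted p = 0.351), PLK2 at 2.62-fold (0.402) and RNU2-59P at a log2 fold change of 3.07 (0.531). MAP2K1, the kinase MEK1, was at 0.293-fold (0.196 to 0.436, adjusted p = 0.121), TOMM70A at 0.298-fold and the zinc exporter SLC30A1 at 0.291-fold (both 0.121). 1 gene was called without LPS+MDMA 1, and once the GC trend of each library was taken out 2 genes fell, MAP2K1 and SLC30A1. The oxidative phosphorylation list was lower, with 21 of 25 estimates negative and 0 genes past the threshold over all genes or over the list alone (camera adjusted p = 7.62e-04, adjusted p = 0.995 with an estimated correlation). The list lost its call without LPS+MDMA 2 or LPS+MDMA 3, when 0 lists passed. The set of LPS genes fixed for this comparison, from LPS+psilocybin against psilocybin, held 0 genes, since that comparison called 0 (edgeR, 1945 at unadjusted p under 0.05). Without psilocybin 1 and LPS+psilocybin 3 it held 760 genes higher with LPS, with a median of 0.21 (camera p = 2.69e-06 in limma, p = 0.213 with an estimated correlation), and 891 lower, with a median of −0.20 (8.42e-07, p = 0.319). With no filter on low counts, all 16 libraries gave medians of 0.13, which did not pass with camera, and −0.39, which did.

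The interaction tests asked whether a compound's effect differed with LPS. For psilocybin 468 genes fell and 55 rose (edgeR). Of the 468, 441 had risen with psilocybin alone, and of the 55, 38 had fallen, where the same psilocybin and PBS libraries enter both comparisons. NFKB2 had an interaction of −3.54 (log2, SE 0.68, adjusted p = 0.0135), JUNB of −4.06 (SE 0.68, 0.01), JUN of −2.47 (SE 0.43, 0.0111), where NFKB2 was at −2.85 without psilocybin 1, and MCL1 of −2.63 (SE 0.46, 0.0111). SOCS3 (0.0121), RELB (0.0124) and OSGIN1 (0.01) fell as well, and these 7 genes kept their calls with each library left out. Over their lists alone 12 of 20 cytokines, 13 of 18 chemokines, 18 of 36 interferon-stimulated and 12 of 25 immediate early genes fell, against 2, 1, 2 and 5 adjusted over all genes. Their camera adjusted p was 2.94e-06, 4.19e-05, 8.22e-07 and 4.1e-08, with adjusted p = 0.476, 0.476, 0.639 and 0.203 with an estimated correlation. In the fit without psilocybin 1 (at 0.776 on the LPS scale) and LPS+psilocybin 3 (at 0.486), 0 cytokines, 0 chemokines, 2 interferon-stimulated and 13 immediate early genes fell over the lists alone by edgeR. The camera adjusted p was then 0.0382, 0.0567, 0.926 and 6.57e-09 (adjusted p = 0.716, 0.716, 0.977 and 0.242 with an estimated correlation), and the interferon median went from −3.59 to 0.10. TNF was at −3.47 (SE 1.17, adjusted p = 0.109). Leaving out psilocybin 1 and LPS+psilocybin 3, 397 genes fell and 41 rose, with 343 of the same genes called. Upper quartile factors, which move the median by 0.182, gave 360 and 116. For MDMA 0 genes passed (edgeR, 694 at unadjusted p under 0.05; DESeq2 gave 4), with the immediate early list lower (1.31e-05, adjusted p = 0.388 with an estimated correlation). The 523 psilocybin calls became 324, 161 and 133 without PBS 1, 2 and 3, 153 without LPS 1-2, 106 without LPS 3, 280 without psilocybin 2 and 149 without LPS+psilocybin 2.

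The compounds, psilocybin a phosphorylated tryptamine and MDMA an amphetamine, were compared directly at 10 µM and 6 h. The deposited library numbers put each group in 1 run, so differences between the compounds cannot be told apart from library number. Without LPS 13 genes were lower with MDMA than with psilocybin and 0 higher (edgeR, 1042 at unadjusted p under 0.05). limma-voom gave 71, DESeq2 234 and a fit of only the groups compared 0. CEBPB, a transcription factor of myeloid cells, had a log2 fold change of −3.72 (SE 0.48, adjusted p = 0.0108), PNRC1 of −2.86 (SE 0.37, 0.0108) and MAP2K1 of −2.16 (SE 0.29, 0.0108), and CEBPB and PNRC1 were chosen after their values were seen. Once psilocybin 1 and LPS+psilocybin 3 were left out, 16 genes were lower and 8 of the 13 were called again, these 3 included. The count became 4 without psilocybin 2, 6 without psilocybin 3, and 0 without MDMA 1 or MDMA 2. The interferon-stimulated list had a median of −3.05, with 27 of 36 genes lower over the list alone (camera adjusted p = 5.54e-09, adjusted p = 0.93 with an estimated correlation), and it was not called without psilocybin 1 and LPS+psilocybin 3. The interval of the difference was 0.561-fold (0.109 to 2.9) for IL8 and 0.355-fold (0.0824 to 1.53) for CCL2, so neither a difference nor likeness is shown for these. With LPS, MAP2K1 alone was lower with MDMA, 0.267-fold (0.183 to 0.391, edgeR adjusted p = 0.0385, 933 at unadjusted p under 0.05; limma-voom gave 0 and DESeq2 56). It was not called without LPS+psilocybin 1, LPS+psilocybin 3 or any LPS+MDMA library, when 0 genes were. Nor was it called with the replicate block or in a fit of only the groups compared. TNF differed by 1.07-fold (0.346 to 3.31) and IL6 by 1.61-fold (0.181 to 14.3).

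Effects of the compounds were correlated across genes, which are not independent replicates. Without LPS Pearson's r over 12403 genes was 0.62 and the covariance 0.482, against a mean r of 0.44 (0.42 to 0.467) and covariance of 0.155 in 20 simulations of unchanged groups with the same PBS libraries. The covariance thus lay 0.327 above the simulated mean. The simulations drew each gene on its own, while deviations of real libraries were shared across genes (r −0.297 to 0.682 between libraries of the same number). The simulated range can therefore be too narrow, and it decides neither an excess without LPS nor a shortfall with LPS. With LPS r was 0.30 and the covariance 0.153, below the simulated 0.569 and 0.306. The 3 PBS and 2 LPS libraries are too few to give each compound controls of its own, so part of any excess may come from the shared controls. With psilocybin 1 and LPS+psilocybin 3 left out, r was 0.72 and 0.47. Leaving out MDMA 1 gave 0.31 without LPS, below the 0.42 to 0.467 simulated with both MDMA libraries. Leaving out LPS 1-2, LPS 3, LPS+psilocybin 2 or LPS+psilocybin 3 gave 0.58, 0.64, 0.16 or 0.47 with LPS.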

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

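Among the tests below, the GC, library, depth and mixture tests were chosen after the result was seen, and the splits of libraries before. With groups of at most 3 libraries no test for a single far value was run.

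The effect of psilocybin differed with and without LPS in 523 genes by the interaction test of edgeR, a difference between groups. Of these 468 fell and 55 rose, and 438 genes passed without psilocybin 1 and LPS+psilocybin 3. JUNB rose 6.53-fold with psilocybin alone and had an interaction of −4.06 (log2), and JUN rose 4.65-fold with an interaction of −2.47.

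Genes differed between psilocybin and PBS, 1092 in all, and 441 of the 468 genes that fell in the interaction had risen with psilocybin. A GC trend across libraries is argued against as the whole cause, since 767 genes passed once it was taken out. A psilocybin effect that is the same with LPS would give a positive median in LPS+psilocybin against LPS. The 774 genes higher with psilocybin, without psilocybin 1 and LPS+psilocybin 3, had a median log2 fold change of −0.54 there. That value rests on 2 LPS libraries and on groups that differ in library number, so it does not decide the point. Library numbers processed together cannot be told apart from treatment, as each group is 1 run of numbers, and the same 774 genes had a median of 0.33 in LPS against LPS+MDMA. An effect of psilocybin on resting monocytes that LPS masks stays open, as does a difference that lies in the PBS libraries, which the other comparisons with PBS share. The 774 genes had a median of 0.81 in MDMA against PBS (91.6% positive) and 1.5 in LPS against PBS (95% positive). These comparisons share the PBS libraries, so they cannot part the 2 explanations. In LPS+MDMA against MDMA, which uses no PBS library, the 774 genes had a median of 0.351 (65.8% positive). MDMA was itself higher than PBS in these genes, so this value does not decide between the explanations either. The median GC content of the 774 genes was 59.1%, against 47.5% for all tested genes.

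The library labelled psilocybin 1 had the LPS genes high, with a position of 0.776. A swap with LPS+psilocybin 1 or 2 is argued against, since the lower of them lay at 0.879 where a swapped library would lie near 0, while one with LPS+psilocybin 3, at 0.486, cannot be told apart because that library may be mixed. Psilocybin raising the LPS genes in each culture is argued against by the other psilocybin libraries, at most at 0.076. A culture that met LPS, or a wrong label, stays a candidate explanation, with a chi-square per degree of freedom of 9.18 to the nearest library with LPS (LPS 3) and 70.4 to the nearest without. No biological explanation beyond psilocybin itself was tested.

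LPS+psilocybin 3 lay midway between libraries with and without LPS. Low depth alone is argued against, because the other LPS+psilocybin libraries thinned to its 299466 counts lay at 0.901 or more. Reads or RNA of many libraries mixed in may be the source, with a chi-square per degree of freedom of 6.37 to the mean profile of the other libraries, taken as exact. With all libraries thinned to its total and the same pairwise statistic, it was 2.68 to a draw from the mean profile and 5.57 to the nearest library, and the other 15 libraries were each nearer to a library. A partial LPS response of that culture cannot be told apart from this: its 14427 detected genes exceed both the thinned libraries (10251 to 11663) and a draw from the mean profile (11344). A mixture of the other 15 libraries alone does not supply 917 of these genes, which had 0 counts in all of them. Genes under 0.5 CPM in the mean profile held 1.64% of its counts, against 0.101% to 0.215% in the thinned libraries. Their mean count was 0.0385 below 1000 bases and 0.714 above 4000 bases. The source of these counts was not tested.

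With LPS the compounds differed in 1 gene. Their 6 libraries make 10 splits, too few for a share under 0.05: 3 of 10 splits gave as many genes, the real one with 1 and the highest other with 4. The 6 libraries of psilocybin and PBS make 10 splits, too few for a share under 0.05: 1 of 10 splits gave as many genes, the real one with 1092, and the highest other gave 0.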

How the results depend on the processing

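The fits without psilocybin 1 and LPS+psilocybin 3, with 18 and 17 libraries, with GC correction and with the block that gave LPS 1-2 the other number were chosen after the data were seen. So was leaving out each library for r of the compounds' effects. Of 3741 alternative values for 247 named values (a gene in a comparison), 3052 kept their direction and side of the threshold, 626 lost a call, 49 gained one and 14 reversed, 0 of them for a value past the threshold. This total includes values that were not called: 205 of the 247 were past the threshold in the main fit. With each library left out, 48 of 112 such values kept their call for LPS against PBS and 12 of 66 for psilocybin against PBS. For the psilocybin interaction 7 of 27 did. Without psilocybin 1 and LPS+psilocybin 3, calls were kept for 111 of 112 values for LPS, 41 of 66 for psilocybin and 16 of 27 for the psilocybin interaction. LPS 3 or LPS 1-2 alone, and a single MDMA library, were assumed to vary like other groups. The cause was not tested for any change below unless stated. Of 4-fold changes in simulated data at these depths and numbers of libraries, 29% to 55% were found, and LPS+psilocybin 3 held 299466 counts. For LPS+MDMA against LPS the filtered fit of 16 libraries gave no LPS gene set. Its medians for genes higher and lower with LPS were 0.13 and −0.39 with no filter on low counts, 0.24 and −0.29 without psilocybin 1, and 0.21 and −0.20 without psilocybin 1 and LPS+psilocybin 3.

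At adjusted p under 0.01, which calls fewer genes by construction, 1070 genes passed for LPS, 191 for psilocybin, 34 for the psilocybin interaction, and 0 for MDMA against psilocybin and for the compounds with LPS (edgeR, 1042 and 933 at unadjusted p under 0.05). With no filter on low counts, which tests 30171 genes, the counts were 1978 for psilocybin, 331 for MDMA, 181 for LPS+psilocybin against LPS, 106 for LPS+MDMA against LPS, 1459 and 243 for the interactions, and 586 and 308 for the compounds without and with LPS. Fitting only the groups compared gave 2 for the MDMA interaction and 0 for both comparisons of the compounds. limma-voom gave 71 and 0 for these. With library weights it gave 5864 for LPS, 4281 for psilocybin, 26 for MDMA, 51 for LPS+MDMA against LPS, 1456 and 1 for the interactions, and 129 and 0 for the compounds. The weight of PBS 2 was 7.01, against 0.858 and 1.35 for PBS 1 and PBS 3, so that library dominates the PBS group there. The lowest weights were 0.276 (LPS+MDMA 3) and 0.319 (psilocybin 1). DESeq2 gave 2008 for psilocybin, 58 for MDMA, 38 for LPS+MDMA against LPS, 1175 and 4 for the interactions, and 234 and 56 for the compounds. In simulated data it called 12 to 19 unchanged genes per comparison, where edgeR called 0 to 3, so part of its further calls may be false. All 18 libraries as deposited gave 1659 for psilocybin, 9 for LPS+MDMA against LPS, 1147 and 1 for the interactions and 84 for MDMA against psilocybin. 17 libraries, with LPS 1 and LPS 2 apart, gave 5, 930, 1 and 26 for the last 4. With the GC trend taken out, 2 genes passed for LPS+MDMA against LPS and 24 for MDMA against psilocybin. Without psilocybin 1 and LPS+psilocybin 3, 0 passed for the compounds with LPS.

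For the gene lists, the estimated correlation left 0 of 14 lists for LPS, 0 of 12 for psilocybin, 2 of 12 for MDMA, and 0 for LPS+MDMA against LPS, both interactions and both comparisons of the compounds. fry gave 3 for MDMA and 0 for LPS+MDMA against LPS, the MDMA interaction and both comparisons of the compounds. The 18 and 17 library fits gave 4 and 4 lists for LPS+psilocybin against LPS and 2 and 2 for LPS+MDMA against LPS, and 17 libraries gave 11 for the psilocybin interaction. Without psilocybin 1 and LPS+psilocybin 3, 4 and 3 lists passed for the compounds without and with LPS, r of the compounds' effects was 0.72 without and 0.47 with LPS, and the median of genes higher with LPS was −0.07 in LPS+psilocybin against LPS.

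The replicate block, which pairs libraries by number, gave 1 list for LPS+psilocybin against LPS and 0 genes for the compounds with LPS, and with LPS 1-2 as number 2 it gave 822 for the psilocybin interaction and 0 for the compounds with LPS. Numbers are not shown to pair libraries: of 16 pairs with the same number 10 correlated above 0.1 (r −0.297 to 0.682). Both pairs did for MDMA against PBS (0.682 and 0.298) and LPS+MDMA against LPS (0.348 and 0.455), and in the other 5 comparisons at least 1 pair did not.

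Leaving out 1 library gave 470 to 2872 genes for LPS, where LPS 1-2 (470), LPS 3 (1593), PBS 2 (1670) and PBS 3 (1791) moved it, and 152 to 1103 for psilocybin, moved by PBS 3 (152), PBS 2 (164), PBS 1 (628) and psilocybin 2 (628). It gave 0 to 1 for MDMA (1 without PBS 3), 0 to 1 for LPS+MDMA against LPS (1 without LPS+MDMA 1), and 106 to 624 for the psilocybin interaction, moved by LPS 3 (106), PBS 3 (133), LPS+psilocybin 2 (149), LPS 1-2 (153), PBS 2 (161), psilocybin 2 (280) and PBS 1 (324). For MDMA against psilocybin it gave 0 to 14 (4 without psilocybin 2, 6 without psilocybin 3, 0 without MDMA 1 or MDMA 2), and for the compounds with LPS 0 to 1 (0 without LPS+psilocybin 1, LPS+psilocybin 3 or any LPS+MDMA library). Lists ranged from 13 to 15 for LPS, 10 to 14 for psilocybin, 6 to 12 for MDMA (6 without MDMA 1) and 0 to 6 for LPS+psilocybin against LPS (6 without LPS 3 or LPS+psilocybin 1, 4 without LPS+psilocybin 2, 1 without LPS 1). They ranged from 0 to 3 for LPS+MDMA against LPS (3 without LPS 3 or LPS+MDMA 1, 0 without LPS+MDMA 2 or 3), 6 to 11 for the psilocybin interaction (11 without psilocybin 3 or LPS+psilocybin 2), and 0 to 9 for the MDMA interaction (0 without MDMA 1, 3 without LPS 1-2 or LPS+MDMA 3). For the compounds the ranges were 1 to 9 without LPS (1 without MDMA 2, 4 without psilocybin 1) and 1 to 5 with LPS (1 without LPS+psilocybin 3 or LPS+MDMA 3, 2 without LPS+MDMA 2, 3 without LPS+MDMA 1). The medians in LPS+psilocybin against LPS ranged from −0.6 to −0.04 for genes higher with LPS (−0.6 without LPS 3, −0.04 without LPS 1-2, −0.09 without LPS+psilocybin 3) and from −0.03, reversed without LPS 1-2, to 0.68, without LPS 3, for genes lower with LPS. r ranged from 0.31 to 0.73 without LPS (0.31 without MDMA 1, 0.53 without psilocybin 2, 0.73 without PBS 1) and from 0.16 to 0.64 with LPS (0.16 without LPS+psilocybin 2, 0.47 without LPS+psilocybin 3, 0.58 without LPS 1-2, 0.64 without LPS 3).

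Reversed values were those of genes not past the threshold. CXCL10 went to 1.1 for MDMA (without PBS 1), to −1.31 for psilocybin (without psilocybin 1, and also without LPS+psilocybin 3), and for LPS+MDMA against LPS to 0.47, 0.07, 0.24 and 0.02 (without LPS 1-2, LPS+MDMA 2, LPS+MDMA 3 and LPS 2). IL1B went to −1.13 for MDMA (without MDMA 1) and to 0.24 and 0.29 for LPS+psilocybin against LPS (without LPS 1-2, and without LPS+psilocybin 3 with or without psilocybin 1). IL6 went to −5.48 for MDMA (without MDMA 1) and to 0.28 and 0.37 for LPS+MDMA against LPS (without LPS 1-2 and LPS+MDMA 3). With each library left out, CXCL10 ran from −1.31 to 6.23 for psilocybin, from −2.96 to 1.1 for MDMA and from −0.59 to 0.47 for LPS+MDMA against LPS, IL6 from −5.48 to 6.07 for MDMA and from −0.91 to 0.37 for LPS+MDMA against LPS, and IL1B from −1.13 to 5.49 for MDMA and from −0.37 to 0.29 for LPS+psilocybin against LPS.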

Other observations

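Other gene lists were tested for LPS against PBS, by tests fixed before the results were seen. Of 14 NRF2 oxidative stress genes 6 rose and 1 fell, with GCLM, which makes glutathione, up 4.96-fold (camera adjusted p = 0.0228, adjusted p = 0.262 with an estimated correlation). Of 14 inflammasome genes 7 rose and 2 fell (9 and 3 over the list alone), with the adaptor PYCARD at 0.137-fold (camera adjusted p = 0.106). PYCARD was not called without LPS 1-2 (adjusted p = 0.101). Of 22 cholesterol genes 4 rose and 2 fell, with LSS up 24.6-fold, a median of −0.18 and a mean of 0.22 (0.787). Of 19 stress response genes 8 rose and 1 fell (10 and 1 over the list alone), with XBP1 up 8.59-fold (0.00431, adjusted p = 0.262 with an estimated correlation). Of 9 proliferation genes 4 fell (5 over the list alone), and of 8 metallothioneins 2 rose (4), MT2A 21.6-fold (0.0114 and 0.0245, adjusted p = 0.262 and 0.499 with an estimated correlation). Of 8 aryl hydrocarbon receptor targets 5 rose (0.00532, adjusted p = 0.0999 with an estimated correlation). Of 14 glucocorticoid-responsive genes 3 rose and 1 fell, with a median of −0.29 and a camera direction that was up (0.787). Of 10 heat shock genes 1 rose and 1 fell (0.31), of 6 serotonin and monoamine genes 2 rose (0.311), of 21 lysosome genes 4 fell (4 rose and 4 fell over the list alone, 0.608) and of 7 dendritic cell markers 2 rose and 1 fell (0.846). Of 13 mitochondrial transcripts 2 rose (0.0785), of 25 ribosomal protein genes 0 passed by edgeR, with 23 estimates negative (0.248), and of 8 histone genes and nuclear RNAs 1 fell (0.305).

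Marker lists with at least 5 tested members did not pass with LPS by camera, and smaller lists were counted only. Of 15 classical monocyte markers 2 fell (0.31), of 11 nonclassical markers 3 rose (0.491), of 25 macrophage markers 1 fell (0.343), and of 13 MHC class II and costimulation genes 1 rose and 3 fell, with CD80 up 117-fold (0.515). 0 of 6 neutrophil markers (0.852) and, untested as lists, 0 of 4 NK, 0 of 4 platelet and 0 of 3 erythroid markers passed by edgeR, and 1 of 3 T cell markers rose (IL7R) and 1 of 3 B cell markers fell (CD22). CD22 was not called without any PBS library, LPS 1-2, LPS 3 or LPS 1 (adjusted p = 0.0548 to 0.283), and IL7R was not called without PBS 2, PBS 3 or LPS 1-2 (adjusted p = 0.0583 to 0.0768). TAAR1 and HTR3A, receptors for trace amines and serotonin, had 0 counts in all libraries, HTR2A had 1 count in all, SLC6A4 0 to 2 per library, HTR2B 0 to 37 and HTR7 4 to 42.

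Groups also parted along another line. Of the 10 ways to part the 6 groups into 3 and 3, the one by LPS separated 247 genes fully, the one with PBS, MDMA and LPS+MDMA on a side 35 (31 lower and 4 higher), and the other 8 from 0 to 13. MAP2K1 ran from 13 to 18.9 CPM in the 8 PBS, MDMA and LPS+MDMA libraries and from 40 to 84.4 CPM in the other 8. SLC30A1 ran from 18.3 to 50.5 and from 53.1 to 133 CPM. This line also follows library numbers. PBS holds numbers 1 to 3, MDMA 25 to 27 and LPS+MDMA 34 to 36. The other side holds 10 to 12 (LPS), 13 to 15 (psilocybin) and 22 to 24 (LPS+psilocybin). Differences between the compounds, those of MAP2K1, SLC30A1, CEBPB and PNRC1 among them, therefore cannot be told apart from library number. LPS+MDMA against MDMA called 889 genes higher and 871 lower. LPS+psilocybin against psilocybin called 0 (edgeR, 1945 at unadjusted p under 0.05), and 941 higher and 960 lower without psilocybin 1 and LPS+psilocybin 3.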
